A study of Mus musculus with 22 samples.

How the data were processed

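Fetal livers of mouse embryos at E14.5 were profiled in 22 samples that fall into 10 groups. Per the labels, the deficient animals (KO) carried floxed Mettl3 and the Cre recombinase driven by the Vav promoter, which acts in blood cells, and the controls (WT) carried the floxed gene without Cre. LSK cells, the sorted fraction without lineage markers and with Sca-1 and c-Kit on the surface, gave bulk RNA-seq of polyadenylated RNA (3 KO and 3 WT libraries), CUT&RUN for the histone mark H3K4me3 (2 and 2) and single-cell RNA-seq (2 and 2). Whole fetal liver gave total RNA (INPUT, 2 and 2) and RNA pulled down with the J2 antibody, which binds double-stranded RNA (J2, 2 and 2). Per the labels, one part of a liver became the input and the other part was lysed for the pull-down. The labels call the libraries biological replicates, so the p-values below measure the spread between samples.

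All deposited values are counts. The bulk and J2 tables hold raw counts of aligned reads per gene, as deposited by the authors. The H3K4me3 table holds raw counts of reads in a window of 3 kb at each transcript start, per the labels. The single-cell table holds deposited counts per gene and cell; whether these are unique molecules is not stated. The submitters' notes name the mouse build GRCm38.p5 and the tools STAR 2.5.3a, Bowtie2 2.2.9, Picard 2.9.0, bedtools, edgeR and Seurat 3.0, without saying which step each made. The counting tool, the annotation release, the strand setting and the removal of duplicates are not stated. All columns of values were matched to a sample. The gene tables list 52459 genes. Of the 14780 genes in the single-cell table, 14776 were matched by symbol to a gene identifier; 10 was the smallest number of cells with a count of a listed gene, and 493 the smallest number of genes in a deposited cell.

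Counts were tested with edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr, libraries were normalized by TMM, and each contrast was tested with the quasi-likelihood F test; p-values were adjusted by the Benjamini-Hochberg method and genes with an adjusted p under 0.05 were called higher or lower. Log2 fold changes are KO over WT, or J2 over INPUT, and SE is the standard error of the log2 fold change. CPM values are TMM-normalized and given as mean ± SD over the libraries of a group. For H3K4me3, 130983 deposited windows gave 123052 distinct windows, and the window with the highest mean count was taken for each of 52453 genes; 10 of these share their exact start with another gene. Windows with a mean log2 CPM of at least 4 (16 CPM) are called marked. The 8 INPUT and J2 libraries were fitted together with 4 group means. The contrasts were INPUT KO over INPUT WT, J2 over INPUT within each genotype, and the difference between those enrichments (the interaction). Input and pull-down of a liver are paired by the protocol, so the interaction is also given with the animal as a block.

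Cells with at least 500 counts and under 20% mitochondrial counts were kept, 15678 of 15707. Counts were summed over the kept cells of a sample and tested as above, since cells are not replicates. For clustering with scanpy 1.11.5, counts were scaled to 10000 per cell and log-transformed. Mitochondrial genes, ribosomal protein genes and 5661 genes called in the bulk comparison were left out, which left 8804 genes, so that clusters would not be defined by the genes that differ. The 2000 most variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 gave the clusters. A cluster took the name of the marker class with the highest mean log2 fold against the other cells if that mean and at least 3 of its markers, each found in at least 5% of the cluster's cells, exceeded 0.25, at least 1 marker was among the 10 leading genes and no other class had more there. This naming rule was set after the data were seen. Numbers of cells per cluster were tested with edgeR, with the total number of cells as library size, and shares have exact binomial (Clopper-Pearson) 95% confidence intervals. Counts were also summed per class where every sample had at least 50 cells of it. Scrublet called 1 cell of 15678 a doublet, and doublets were not removed. Whether they had been removed before deposit is not stated.

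Lists of genes for 26 functions and cell types were written before the data were examined, as were the comparisons, the tests, the alternatives listed first below and the rule for naming genes. Each list was tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01, over lists with at least 5 tested members, and adjusted over the lists of a comparison. The same test with the correlation estimated per list, and fry, were run beside it; fry tests whether a list's genes move on balance one way and compares it with no other genes. Numbers of list members called are given over all genes and, where stated, adjusted over the list alone. The interferon-stimulated and double-stranded RNA sensing lists share 15 genes. With the correlation estimated, 2 list calls held over the 7 comparisons: interferon-stimulated genes in INPUT, and MYC targets and ribosome biogenesis in the J2 enrichment of KO libraries.

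The text names Mettl3 in every assay, up to 10 genes per direction with the largest log2 fold change among those called, with a log2 CPM of at least 2 and with every library of one group above every library of the other, and up to 4 called members of each list. Predicted and clone-named genes stay in the counts only, and some genes that passed are not reported here. Where fewer than 5 genes passed in a direction, the 5 with the smallest p are given as values that did not pass. H19 and individual members of cell classes were chosen after their values were seen. A fold against a group at 0 in every library is a lower bound, computed against a floor of 3 counts over the group; a group with 1 to 3 counts is given as a ratio with its 95% counting interval. Intervals and floors cover counting error only. Called genes of comparison pairs were compared with Fisher's exact test, two-sided, among genes tested in both.

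The alternatives fixed beforehand were RLE factors, library size only, DESeq2 1.42.0, no low-count filter, at least 1 CPM, the replicate number as a block, leaving out each library in turn, all distinct windows, only the 4 libraries of a contrast, J2 libraries without inputs, cells of at least 1000 counts, and other clusterings. Alternatives chosen after seeing the data were marked windows only, the sex of the library as a term, leaving out abundant noncoding loci, genes of chromosomes X and Y or the 5% of cells with most counts, clustering without sex transcripts, and DESeq2 within classes. Input and pull-down of one animal, paired by the protocol, correlated at 0.129 in WT and 0.00797 in KO after centring within groups. In raw counts, no pair of libraries within a group was identical.

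The method was tested on simulated data in which 67, 67 and 66 genes changed 1.5-, 2- and 4-fold in one group. Of these, the test recovered 67.2%, 80.6% and 100% in bulk, 16.4%, 55.2% and 98.5% for H3K4me3, 0%, 0% and 47.0% in INPUT, and 0%, 5.97% and 74.2% in single-cell sums. For the interaction it recovered 0%, 0% and 18.2%, and for J2 over INPUT in WT 0%, 1.49% and 25.8%. The changed genes were drawn only from those above a floor of mean counts. Few genes changed at once, while the real J2 comparisons called 3503 in WT and 4462 in KO. That many calls loosen the cutoff on p, so real recovery can differ. False calls were 17 of 182 in bulk, 4 of 117 for H3K4me3, 1 of 32 in INPUT, 1 of 19 and 2 of 19 for J2 in WT and KO, 1 of 13 for the interaction and 10 of 63 in single-cell sums, so their share exceeded 5% except for H3K4me3 and INPUT. Depth per library is given with the results. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9.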

Results

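The samples came from mouse fetal liver at E14.5, from animals lacking Mettl3 in blood cells (KO) and from controls with the gene intact (WT). Mettl3 is the catalytic subunit of the enzyme complex that writes N6-methyladenosine (m6A) into messenger RNA, and the study asked what that modification does in blood formation. LSK cells, the sorted fraction that holds blood stem cells and multipotent progenitors, were read by bulk RNA-seq in 3 KO and 3 WT libraries. The same fraction gave 2 KO and 2 WT libraries each of H3K4me3 CUT&RUN and of single-cell RNA-seq. CUT&RUN releases DNA next to a bound antibody, and H3K4me3 is a histone mark found at active gene starts. Whole fetal liver gave 2 KO and 2 WT libraries each of total RNA (INPUT) and of RNA bound by J2, an antibody against double-stranded RNA.

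Bulk libraries held 40.6, 27.7 and 33.2 M counts (KO 1 to 3) and 30.3, 35.9 and 20.1 M counts (WT 1 to 3). The strongest H3K4me3 window of each gene summed to 13.8 and 14.45 M counts in KO and 14.3 and 11.5 M in WT. INPUT libraries held 4.12 and 3.41 M (KO) and 3.10 and 3.18 M (WT), and J2 libraries 5.25 and 4.71 M (KO) and 4.02 and 3.87 M (WT). Single-cell libraries kept 4920 and 3884 KO cells and 2731 and 4143 WT cells, with medians of 1478.5, 2134.5, 2099 and 1560 counts per cell. Transcripts of the X-inactivation gene Xist and of Y-linked genes showed which sexes a library held. Bulk KO 1 held female transcripts only, bulk WT 3 male ones only, and the other 4 bulk libraries both. In INPUT and J2 alike, KO 1 and WT 2 were male and KO 2 and WT 1 female. Both single-cell KO libraries were female and both WT libraries male, so sex and genotype cannot be told apart there.

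The bulk comparison asked which transcripts differ in LSK cells without Mettl3. Mettl3 itself fell. Interferon-stimulated genes, which cells switch on after sensing virus or their own double-stranded RNA, made up most of the genes with the largest rise. Among them were the chemokine gene Cxcl10, the RNA-binding Ifit1, the ubiquitin-like modifier Isg15 and Rtp4. Genes of granulocyte progenitors, such as Ms4a3, rose as well, while lymphoid receptor genes such as Il7r and the antigen-presentation gene H2-Aa fell.

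Mettl3 (ENSMUSG00000022160, chromosome 14) fell by 2.91 on the log2 scale (SE 0.17, adjusted p 1.6e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), from 39.7 ± 5.7 to 5.32 ± 1.1 CPM (SD, n = 3). Cxcl10 was higher by 4.24 (SE 0.30, adjusted p 2.8e-05) and Iigp1, an interferon-inducible GTPase gene, by 3.71. Ifit1 rose from 2.85 ± 0.61 to 36.7 ± 11 CPM, and Isg15 (ENSMUSG00000035692, chromosome 4) from 4.14 ± 0.24 to 45.4 ± 12 CPM. Rtp4 (ENSMUSG00000033355, chromosome 16) rose from 12.2 ± 0.71 to 104 ± 21 CPM, a log2 fold change of 3.08 (SE 0.15, adjusted p 8.8e-06). Ifi44, Oasl1 and Usp18, also induced by interferon, were higher by 3.15, 3.05 and 2.94. Ms4a3, a gene of granulocyte-monocyte progenitors, rose by 2.94, from 7.19 ± 1.7 to 55.9 ± 6.2 CPM, and the guanine deaminase gene Gda by 3.12. The noncoding RNA Meg3 had the largest fall at -4.22 (SE 1.06, adjusted p 0.011), from 10.8 ± 15 to 0.588 CPM, and its call was lost without KO 1 (adjusted p 0.0579). H2-Aa, for presenting antigen to T cells, fell from 22.1 ± 11 to 1.99 ± 0.33 CPM, a change of -3.48, and H2-Eb1 of the same family by -2.79.

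The phospholipase-like gene Plbd1 (-3.80), the adhesion gene Cadm1 (-3.02) and Zfp366 of dendritic cells (-2.83) also fell, as did Slc26a1 (-3.21) and Stc1 (-2.79). In all, 6367 of 14405 genes were called by edgeR, 3114 higher and 3253 lower in KO. DESeq2 called 6326. Scaling by library size alone moved the median of all genes from -0.02 to -0.11 and the split to 2463 higher and 4143 lower of 6606. Leaving out 1 library gave 4677 (without KO 3) to 6796 (without WT 3) genes.

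**Figure D1:**
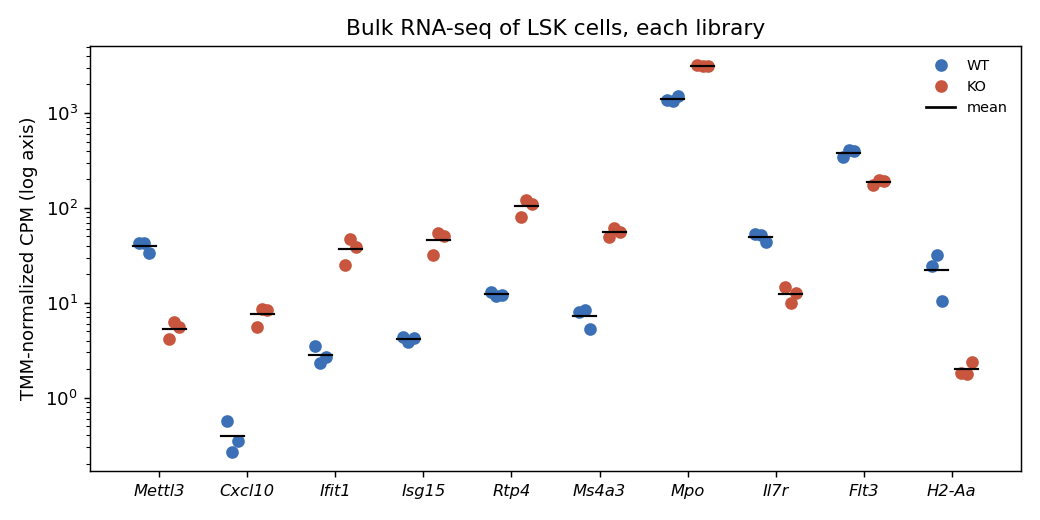
Each point is the TMM-normalized CPM of one bulk LSK library (log axis) for 10 genes, with WT blue, KO red and a black line at the mean of 3 libraries. Rtp4 stood at a mean of 12.2 CPM in WT and 104 in KO, and Il7r at 49.6 and 12.4.

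Responses to foreign RNA and to stress were read from lists of known genes. Interferon-stimulated genes were higher as a group, and so were genes that sense double-stranded RNA, such as Dhx58, and the m6A machinery other than Mettl3, such as the writer component Wtap. Genes that build ribosomes, many of them targets of Myc, were higher too. Inhibitors of the cell cycle that keep stem cells quiescent, such as Cdkn1c, were lower.

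Of 69 interferon-stimulated genes tested, 58 were called higher and 0 lower (63 and 0 adjusted over the list alone), with a median log2 fold change of 0.97 and a camera adjusted p of 6.78e-38. Among double-stranded RNA sensing genes, 17 of 28 were higher and 1 lower (17 and 4 adjusted over the list alone; median 0.45, adjusted p 5.15e-09). Oasl2 and Oas1a, which make 2-5A to activate an RNA-degrading enzyme, were each higher by 2.24, and the helicase gene Dhx58 by 1.34. The integrated stress response, which slows translation, had 15 of 32 genes higher and 3 lower (16 and 3 adjusted over the list alone; median 0.22, adjusted p 0.00373), with Cebpb rising from 24.8 to 70.2 CPM and the amino-acid transporter genes Slc7a5 and Slc3a2 by 0.72 and 0.59. Of 23 genes that write, read or erase m6A, 12 were higher and 1 lower (12 and 3 adjusted over the list alone; median 0.32, adjusted p 0.000104), with Wtap rising by 1.36 from 98.2 to 252 CPM and the reader gene Ythdf2 by 1.05. For MYC targets and ribosome biogenesis, 31 of 38 were higher and 1 lower (31 and 1 adjusted over the list alone; median 0.39, adjusted p 4.2e-11), with Polr1b, for ribosomal RNA synthesis, higher by 1.11 and Myc by 0.86, from 294 to 533 CPM. Of 15 cyclin-dependent kinase inhibitor and quiescence genes, 7 were lower and 1 higher, also when adjusted over the list alone (median -0.53, adjusted p 0.0112). Cdkn1c was lower by -1.31 and the retinoblastoma gene Rb1 by -0.93.

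Lists of p53 targets (7 higher and 9 lower of 29, adjusted p 0.516), inflammatory NF-kB genes (5 and 1 of 20, 0.254), necroptosis and pyroptosis genes (9 and 3 of 18, 0.0888) and SOCS genes (2 and 2 of 8, 0.633) were not called by camera. Neither were cell cycle genes (6 and 7 of 42, 0.763), H3K4 methylation machinery (6 and 3 of 19, 0.826), immediate early genes (4 and 1 of 21, 0.763), mitochondrially encoded transcripts (0 of 7, 0.418) or ribosomal protein genes (2 and 0 of 85, 0.866). Single members passed: the p53 targets Trp53inp1 and Sesn1 were lower by -1.34 and -0.96, and the death-signalling kinase gene Ripk1 was higher by 0.92. With 1 library left out some of these lists were called: without WT 1, immediate early genes, whose median turned from -0.60 to 0.44 (0.00936), and inflammatory genes (0.048), and without KO 1, necroptosis and pyroptosis genes (0.0423). For inflammatory genes the median, -0.05, and the mean, 0.09, differed in sign.

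Genes of blood lineages and of other liver cells moved in separate directions. Granule protease genes of granulocytes, such as Ctsg, Prtn3 and Mpo, were higher in KO. Genes of lymphoid cells, such as the cytokine receptor genes Il7r and Flt3, and of dendritic cells were lower, as were stem cell and erythroid genes. Endothelial and stromal genes, which LSK sorting should leave behind, were lower as well.

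Of 22 granulocyte genes, 11 were higher and 0 lower (12 and 0 adjusted over the list alone; median 0.49, camera adjusted p 6.97e-11). Ctsg rose by 2.32 from 24.9 to 124 CPM, Prtn3 by 1.67 from 126 to 400 CPM, and Mpo by 1.17 from 1408 to 3161 CPM. Mast cell and basophil genes had 6 of 10 higher and 1 lower (the same adjusted over the list alone; median 0.98, adjusted p 0.00639), with Cma1 at least 16.9-fold higher because all WT libraries held 0 counts, and the histamine enzyme gene Hdc higher by 1.39. Lymphoid genes had 25 of 28 lower and 1 higher, also adjusted over the list alone (median -1.16, adjusted p 1.81e-13). Il7r (ENSMUSG00000003882, chromosome 15) fell from 49.6 ± 4.9 to 12.4 ± 2.4 CPM, a change of -1.99 (SE 0.14, adjusted p 2.9e-05), the thymus-homing receptor gene Ccr9 by -2.33, and Flt3 from 382 ± 34 to 187 ± 13 CPM. Dendritic cell genes had 14 of 16 lower and 1 higher, also adjusted over the list alone (median -1.81, adjusted p 5.35e-07). Stem and multipotent progenitor genes had 23 of 34 lower and 3 higher (25 and 3 adjusted over the list alone; median -0.53, adjusted p 0.000104), with Hoxa5 at -1.10. Erythroid genes had 15 of 30 lower and 1 higher (16 and 1 adjusted over the list alone; median -0.45, adjusted p 0.0012). Monocyte and macrophage genes had 15 of 27 lower and 4 higher (18 and 4 adjusted over the list alone; median -0.78, adjusted p 0.0315), a list call lost in 4 of 9 alternatives. These were library size alone (0.0892) and leaving out WT 1 (0.224), WT 2 (0.0708) or KO 1 (0.0586).

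Endothelial genes had 8 of 15 lower and 0 higher (10 and 0 adjusted over the list alone; median -0.57, camera adjusted p 0.0141), among them Cdh5 at -1.24, and stromal genes 8 of 10 lower and 0 higher, also adjusted over the list alone (median -1.28, adjusted p 0.0102), among them the collagen gene Col3a1 at -2.80. Megakaryocyte genes (3 higher and 6 lower of 23, adjusted p 0.633) and hepatocyte genes (1 and 1 of 22, 0.139) were not called, though the latter were called lower without WT 2 (median -1.33, 0.0192) or WT 3 (-1.36, 0.0435). With the correlation between genes estimated, none of the 15 list calls of the bulk comparison held, the adjusted p ranging from 0.192 for interferon-stimulated genes to 0.753 for monocyte and macrophage genes.

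**Figure D2:**
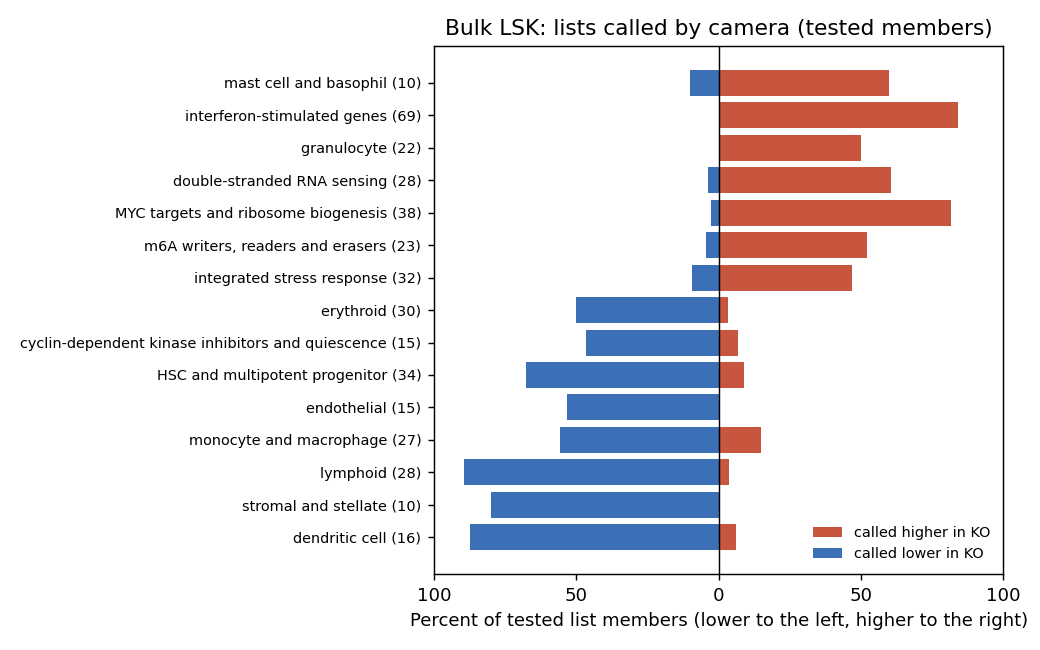
Bars give the percent of tested members called higher (right) or lower (left) in KO bulk LSK libraries for the 15 lists called by camera with a preset correlation. Of interferon-stimulated genes 58 of 69 were higher, and of lymphoid genes 25 of 28 lower.

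The H3K4me3 comparison asked whether the mark at gene starts differed in LSK cells. Starts of antiviral genes carried more of it in KO, chiefly the oligoadenylate synthetase genes Oas1g and Oas2 and the interferon-stimulated Rtp4. Starts of granulocyte genes such as the iron-binding Lcn2 carried more as well. The starts of Il7r and of Rag1, the recombinase gene of developing lymphocytes, carried less. No difference was detected at the start of Mettl3 itself.

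At Mettl3 the window (chromosome 14, start at 52305128, GRCm38.p5) had a log2 fold change of 0.24 (SE 0.21, adjusted p 0.396 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Oas1g (chromosome 5, 120887582) rose by 2.45 (SE 0.20, adjusted p 6.2e-31), from 3.02 ± 0.82 to 16.7 ± 0.71 CPM (SD, n = 2), and Oas2 (chromosome 5, 120749853) by 2.38, from 4.02 to 21.0 CPM. Rtp4 (chromosome 16, 23609919) rose by 1.79 (SE 0.19, adjusted p 6e-18). Oas1a, Ecm1, Cd177 of neutrophils, Col6a3, Il18bp, Lgals3bp, Elfn2 and Oas3 were higher by 1.83, 1.78, 1.56, 1.47, 1.46, 1.42, 1.41 and 1.37. The focal adhesion gene Tns1 (chromosome 1, 74001567) fell most, by -1.79 (SE 0.18, adjusted p 9.5e-20), from 37.1 to 10.7 CPM. Il1rl1, a receptor gene of mast cells, fell by -1.71, Enpp3 of basophils by -1.53 and Acsl6 by -1.47. Il7r (chromosome 15, 9529876) fell by -1.62 (SE 0.18, adjusted p 8.8e-15), a call that DESeq2 did not make (0.247).

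Calls followed the strength of a window. Of 51038 windows tested, edgeR called 4024, with 1648 higher and 2376 lower, and DESeq2 802, with 759 higher and 43 lower. Windows with a mean log2 CPM of 0 to 1 had a median change of -0.55, with 0 called higher and 896 lower, while those of 4 to 5 had a median of 0.26, with 526 higher and 54 lower. Counts in the 15957 marked windows made up 91.3% and 89.3% of the total in KO and 88.3% and 85.7% in WT. On marked windows alone, a choice made after the data were seen, 336 were called higher and 330 lower. RLE scaling gave 1997 higher and 1991 lower and moved the median over all windows from -0.15 to -0.04, and library size alone gave 1305 and 3310 and a median of -0.40. The count fell to 1302 without KO 1 (909 higher and 393 lower), 2140 without KO 2 (1488 and 652) and 1078 without WT 2 (677 and 401), and was 3855 without WT 1 (2811 and 1044), so most calls were higher with any library left out.

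**Figure D3:**
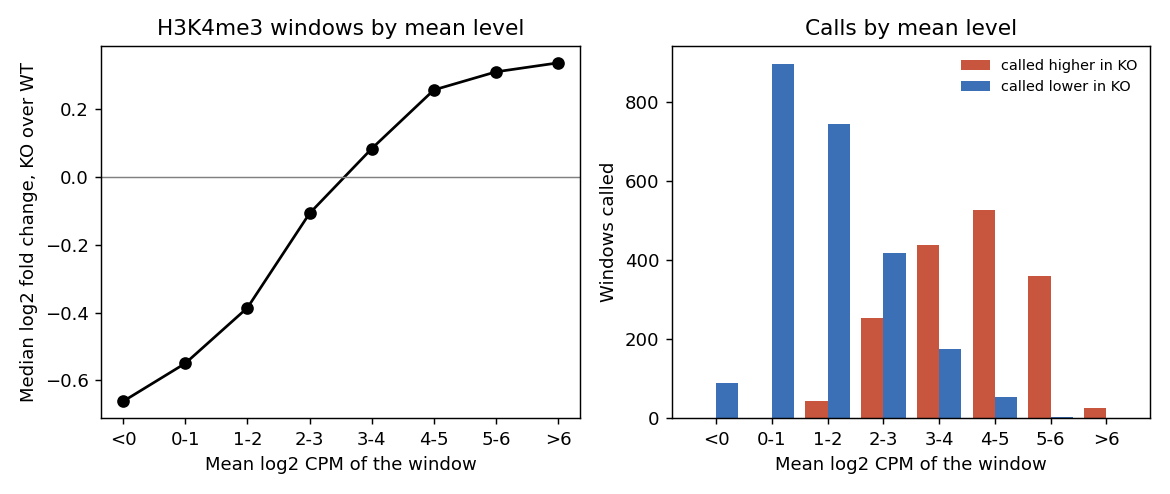
The left panel gives the median log2 fold change (KO over WT) of H3K4me3 windows by their mean log2 CPM, and the right panel the number of windows called higher (red) or lower (blue) in each bin. The median went from -0.66 in the weakest bin to 0.33 in the strongest.

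Interferon-stimulated genes and granulocyte genes led the H3K4me3 lists, and lymphoid genes were the only list called lower. Strong windows as a class were higher, and so were lists of active genes of many kinds over all windows. Most of these calls were not made on marked windows. Of 69 interferon-stimulated genes, 33 were higher and 2 lower (46 and 2 adjusted over the list alone; median 0.57, camera adjusted p 2.56e-35), and on marked windows 21 of 55 were higher and 0 lower (median 0.27, adjusted p 1.57e-26, 0.379 with the correlation estimated). Double-stranded RNA sensing genes had 14 of 28 higher and 0 lower (16 and 0 adjusted over the list alone; 0.58, 4.38e-25) and 10 of 25 on marked windows. Granulocyte genes had 15 of 24 higher and 0 lower (21 and 1 adjusted over the list alone; 0.68, 2.09e-22) and 11 of 19 on marked windows; Lcn2 was higher by 1.33, Ms4a3 by 1.31 and S100a8 by 1.18. Lymphoid genes had 6 of 30 lower and 0 higher (8 and 0 adjusted over the list alone; -0.23, 0.00457; 5 of 17 lower on marked windows, 1.66e-05), a call lost without WT 1 (0.567) or KO 2 (0.159); Rag1 was lower by -1.39 and Blnk, for B cell signalling, by -1.05. Erythroid genes had 3 of 30 lower and 0 higher (adjusted p 0.261; their median of -0.11 became 0.00 with RLE scaling) but 9 of 24 lower on marked windows (adjusted p 1.73e-15), and the list was also called lower with library size alone (1.32e-06) and without WT 2 (0.00595) or KO 1 (0.00338).

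The other 15 lists called higher had few members called, and on marked windows 12 of them were not called. The largest numbers were 7 of 24 megakaryocyte genes (adjusted p 0.000222; their median of 0.17 became -0.08 with library size alone), 6 of 34 integrated stress response genes (7.27e-09), 3 of 29 p53 targets (1.19e-06), 3 of 30 inflammatory genes with 1 lower (0.000209) and 2 of 35 stem and progenitor genes (8.71e-05). SOCS genes (2 of 8, 0.000955), endothelial genes (2 of 18 with 1 lower, 0.0181), necroptosis and pyroptosis genes (1 of 18, 0.000955), immediate early genes (1 of 22, 6.17e-08) and quiescence genes (1 of 17, 1.89e-05) followed. Genes for m6A (0 of 23, 2.29e-05), the cell cycle (0 of 42, 1.82e-05), MYC targets (0 of 38, 2.82e-08), H3K4 methylation (0 of 19, 1.06e-05) and ribosomal proteins (0 of 88 higher and 1 lower, 3.67e-10) had no member called higher. Adjusted over the list alone, inflammatory genes had 5 higher, SOCS genes 3 and quiescence genes 0, and the others moved by at most 1. On marked windows the adjusted p was 0.638 for megakaryocyte genes, 0.211 for the stress response, 0.391 for p53 targets, 0.905 for stem and progenitor and for m6A genes, 0.190 for SOCS genes, 0.386 for necroptosis and pyroptosis genes, 0.263 for quiescence genes, 0.320 for MYC targets and for ribosomal proteins, 0.243 for H3K4 methylation and 0.404 for endothelial genes. Inflammatory and immediate early genes were still called higher there, and cell cycle genes lower. Mast cell (3 higher and 1 lower of 17, 0.18), monocyte (4 and 5 of 27, 0.973), dendritic (2 and 3 of 17, 0.641), hepatocyte (3 and 1 of 29, 0.338), stromal (2 and 2 of 20, 0.641) and mitochondrial genes (0 of 12, 0.136) were not called, though the last were called higher without WT 2 (0.00573) or KO 1 (0.0104). With the correlation estimated, none of the 19 list calls held, the adjusted p being 0.611 to 0.637. The endothelial call was lost with library size alone (0.22) and without WT 2 (0.0671) or KO 2 (0.0554), and the stem and progenitor call without WT 2 (0.491).

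Bulk RNA and H3K4me3 moved together at part of the genes. Among 14395 genes tested in both, 257 were higher in both where 148.8 were expected (odds ratio 2.26, p 5.9e-22 by Fisher's exact test, two-sided), and 133 were lower in both where 49.7 were expected (odds ratio 5.42, p 5.7e-34). Opposite calls were 7 for genes higher in bulk and 115 for genes lower in bulk. Of genes called in bulk, 97.2% of the higher but 22.6% of the lower ones had the same sign in H3K4me3 (62.1% and 56.9% on marked windows). On marked windows 137 were higher in both. Higher in both were 97 without H3K4me3 WT 2, 117 without KO 1 and 539 without WT 1, and lower in both 59 without WT 1, 79 without KO 1 and 55 without KO 2. Across genes, which are not independent replicates, Spearman's correlation of log2 fold changes was 0.25, and 0.20 on marked windows.

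The single-cell comparison asked the same question with cells read one by one. Interferon-stimulated genes were again higher as a list in libraries labelled KO, and lymphoid and dendritic genes lower. Rtp4 and Oasl2 had the same direction as in bulk without passing. Xist, which silences one X chromosome in females, was the only gene called by edgeR. Mettl3 tags did not fall.

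Mettl3 had 34.8 ± 2.2 CPM in WT and 58.3 ± 8.6 CPM in the libraries labelled KO (SD, n = 2), a log2 fold change of 0.74 (SE 0.17) that did not pass (adjusted p 0.25 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Xist was at least 1587-fold higher (0 against 310 ± 24 CPM, adjusted p 0.024), in libraries of different sex. Of 13374 genes tested, 1932 had a raw p under 0.05 and edgeR called 1; DESeq2 called 310. Rtp4 was higher by 3.09 (SE 0.26, adjusted p 0.10), at 138 ± 4.7 against 16.0 ± 5.4 CPM, Oasl2 by 2.75 (adjusted p 0.075) and Usp18 by 2.61 (0.075), none of which passed. The lymphoid gene Ly6d was lower by -2.63 (0.075) and the Y-linked Ddx3y at least 246-fold lower (0.075), without passing. The count was 0 without genes of chromosomes X and Y and 0 without any 1 of the 4 libraries.

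With its preset correlation, camera called lists where single genes did not pass, but fry called 0 of them. Of 67 interferon-stimulated genes, 0 were called over all genes and 51 higher and 0 lower adjusted over the list alone (median 1.18, camera adjusted p 3.44e-61). Double-stranded RNA sensing genes had 11 of 27 higher adjusted over the list alone (0.86, 7.17e-16), m6A genes 10 of 23 (0.45, 1.99e-07) and MYC targets 6 of 38 (0.34, 2.87e-09), each with 0 lower. Lymphoid genes had 12 of 25 lower adjusted over the list alone (-1.41, 9.21e-16), dendritic genes 6 of 14 lower and 1 higher (-1.70, 2.75e-09), and monocyte and macrophage genes 6 of 16 lower (-0.83, 5.5e-07). Ribosomal protein genes (-0.33, 1.33e-07), quiescence genes (-0.43, 0.00984) and integrated stress response genes (0.29, 0.0187) were called with 0 members passing. Leaving out WT 1 ended the ribosomal (0.094) and quiescence (0.269) calls, KO 2 the quiescence call (0.0576), and WT 2 (0.144) or KO 1 (0.125) the stress response call. With the correlation estimated, none of the 10 list calls held (adjusted p 0.357 to 0.85). The other 16 lists were not called, with adjusted p from 0.101 for granulocyte genes to 0.994 for stromal genes, but 8 of them were called with 1 library left out. Granulocyte genes were higher without WT 1 (0.00267) or KO 2 (1.16e-08), erythroid genes lower without WT 2 (0.00013) or KO 1 (6.89e-11), stem and progenitor genes lower without WT 1 (0.0149) or KO 2 (0.000463), and mitochondrial transcripts lower without WT 2 (0.000953) or KO 1 (0.00448). Immediate early genes were higher without WT 1 (median 1.44, 0.000241) and lower without WT 2 (-1.50, 1.74e-05) or KO 1 (-1.72, 0.00938). Without WT 2, p53 targets (0.0459) and megakaryocyte genes (0.0362) were lower and necroptosis and pyroptosis genes (0.0319) higher.

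Bulk and single-cell changes ran the same way across 11847 genes tested in both, with a Spearman correlation of 0.667, genes not being independent replicates. 0 genes were called in the same direction in both at the main threshold. Of genes called in bulk, 93.6% of the higher and 85.1% of the lower ones had the same sign in single cells.

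Within classes of cells, the single-cell data asked whether interferon-stimulated genes were higher in 1 cell type or in several. Rtp4 rose in the summed counts of erythroid-like, stem and progenitor-like, lymphoid-like and monocyte-like cells. Ifitm3, which keeps viruses from entering cells, rose in the first 3 of these. Il7r fell in the stem and progenitor-like class, and the antigen-presentation gene H2-Aa in the monocyte-like class.

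Mettl3 was called in none of the classes (log2 fold change 0.76 erythroid-like, 0.30 stem and progenitor-like, 1.11 lymphoid-like, 0.25 megakaryocyte-like and 0.53 monocyte-like). The stem and progenitor-like class took its name from a low mean marker log2 fold of 0.42. Its cells had a median of 1.94 times their samples' median counts. In the stem and progenitor-like class, edgeR called 158 of 10641 genes, 109 higher and 49 lower, and 27 of 65 interferon-stimulated genes were higher (49 adjusted over the list alone; median 1.13, camera adjusted p 6.74e-53, 0.0940 with the correlation estimated). Rtp4 rose there by 3.06 (SE 0.24, adjusted p 4.4e-05), with 11.4 and 22.1 CPM in the WT libraries and 170 and 147 CPM in those labelled KO. Of 21 lymphoid genes in this class, 5 were lower (14 adjusted over the list alone; -1.39, 1.59e-16, 0.180 with the correlation estimated), with Il7r at -1.70 (SE 0.22, adjusted p 0.0043). Erythroid-like cells had 242 of 6625 genes called, 147 higher, with 20 of 35 interferon-stimulated genes higher (28 adjusted over the list alone; 1.65, 4.28e-34, 0.381 with the correlation estimated). Rtp4 was at 0 and 3.40 CPM in the WT libraries and 83.3 and 47.4 CPM in those labelled KO. Erythroid genes had 7 of 23 lower in these cells (12 adjusted over the list alone; -0.75, 9.36e-11, 0.398 with the correlation estimated).

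Lymphoid-like cells had 44 of 8477 genes called, with 10 of 49 interferon-stimulated genes higher (30 adjusted over the list alone; 1.02, 1.84e-37, 0.209 with the correlation estimated). Monocyte-like cells had 157 of 5257 genes called, with 8 of 33 interferon-stimulated genes higher (14 adjusted over the list alone; 0.80, 4.73e-10, 0.321 with the correlation estimated). H2-Aa in monocyte-like cells was at 388 and 41.7 CPM in the WT libraries and 9.38 and 0 CPM in those labelled KO (adjusted p 0.0057 by edgeR). With all variable genes kept, a separate cluster of 121 cells led by H2-Aa held 93 and 20 WT cells and 5 and 3 KO cells. Whether such cells carry the fall was not tested. Megakaryocyte-like cells had only Xist called of 3400 genes, 211 with a raw p under 0.05, and DESeq2 called 1; their interferon-stimulated genes had 0 of 14 called (5 adjusted over the list alone; 0.62, 1.55e-08, 0.336 with the correlation estimated). Granulocyte genes had members called higher in 3 of these classes: 3 of 8 in erythroid-like cells (camera adjusted p 0.000828, 0.443 with the correlation estimated), 3 of 13 in lymphoid-like cells (0.0002, 0.371) and 4 of 9 in monocyte-like cells (4.1e-05, 0.325). Ctsg in erythroid-like cells was at 13.6 and 23.8 CPM in the WT libraries and 104 and 6.78 CPM in those labelled KO. RNA carried over from other cells was not estimated, so a rise in the sum of a class cannot be assigned to its own cells alone. Whether effects differed between classes was not tested. With cells of at least 1000 counts, lymphoid-like cells had 29 calls, against 44. Over the classes 602 calls were made, 255 with DESeq2 (34 in erythroid-like, 136 in stem and progenitor-like, 44 in lymphoid-like and 40 in monocyte-like cells) and 1186 without WT 2. Left-out libraries gave 82 (WT 1), 105 (KO 1) and 576 (WT 2) calls in erythroid-like cells, 543 (KO 2) in stem and progenitor-like cells, 12 (KO 1), 142 (KO 2) and 189 (WT 2) in lymphoid-like cells, 248 (WT 2) in monocyte-like cells and 12 (KO 1) and 14 (KO 2) in megakaryocyte-like cells.

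**Figure D4:**
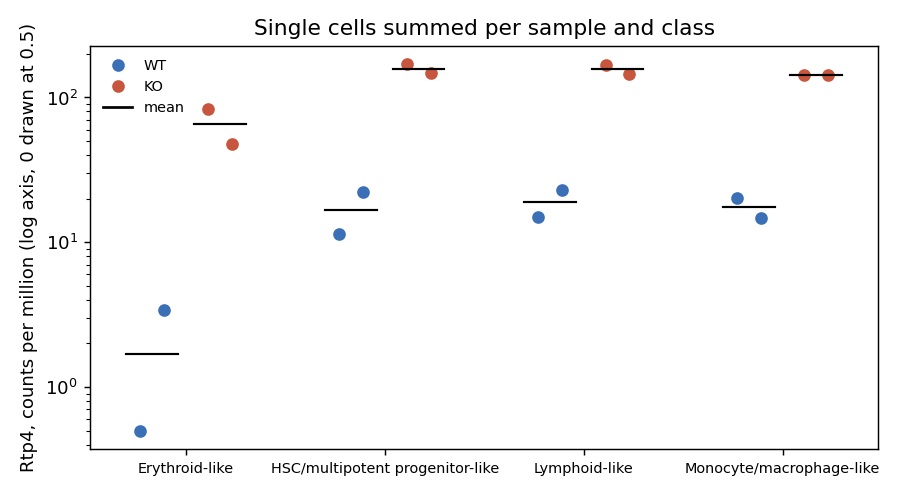
Points give Rtp4 CPM (log axis) in each single-cell sample, summed over the cells of 4 classes, with 0 drawn at 0.5. In the stem and progenitor-like class the WT samples lay at 11.4 and 22.1 and those labelled KO at 170 and 147.

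In the main clustering, shares of stem and progenitor-like and of erythroid-like cells differed more between replicates of a genotype than between genotypes. Replicates 1 and 2 stood in the same order in both genotypes for each of these shares. That clustering left out the genes called in bulk, many lymphoid and dendritic genes among them, so it could miss a shift in those cell types. Stem and progenitor-like cells, marked by Angpt1, made up 6.70% (95% exact binomial interval 5.79 to 7.70) and 24.5% (23.2 to 25.8) of WT cells and 11.7% (10.8 to 12.6) and 34.7% (33.2 to 36.3) of KO cells. Angpt1 was the only marker of the class among the 10 leading genes, and the cells were deep, at a median of 1.94 times their samples' median counts. Lymphoid-like cells, marked by Mzb1, Ighm and Cd79b, made up 16.3% (14.9 to 17.7) and 22.1% (20.9 to 23.4) of WT cells and 6.69% (6.01 to 7.42) and 17.4% (16.2 to 18.6) of KO cells. Erythroid-like cells made up 10.0% and 2.87% of WT and 13.9% and 2.11% of KO cells. These shares depended on the clustering: lymphoid-like cells made up 3.43% of WT 2 and 1.67% of KO 2 at doubled resolution. With all variable genes kept, lymphoid-like cells made up 25.9% and 19.3% of WT cells and 4.92% and 7.54% of KO cells. Monocyte-like cells then made up 9.89% and 11.4% of WT and 2.48% and 2.47% of KO cells, and granulocyte-like cells 4.21% and 1.81% against 32.3% and 5.77%. Most of these granulocyte-like cells formed a cluster of 1857 led by Ms4a3, Ctsg and Hspa1a, with 1483 of them from KO 1. A smaller cluster of 145, led by S100a9, S100a8 and Camp, held 30 and 6 WT and 105 and 4 KO cells. Genes called in bulk helped to define the clusters here, so these shares can also follow changes in expression. Stem and progenitor-like (17.3% and 54.1% against 12.9% and 52.8%) and erythroid-like shares (10.1% and 3.38% against 12.5% and 2.52%) still varied most between replicates. No cluster was called there either (smallest adjusted p 0.209 by edgeR). Granulocyte-like cells numbered 28 in KO 2 and were not tested as a class. A cluster with high Fos, Egr1 and Klf2, genes that respond to handling, took 43.0% and 0.82% of WT cells and 12.4% and 0.64% of KO cells and was given no name. With other unnamed clusters it held 58.0% and 38.1% of WT cells and 55.4% and 35.8% of KO cells, which no test within a class covered. Of 9 clusters, edgeR called 0 (smallest adjusted p 0.911), and 0 had a raw p under 0.05; no other tool was run on the shares.

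The INPUT comparison asked what differed in total RNA of whole fetal liver. Interferon-stimulated genes such as Isg15, Ifit1 and Rsad2, the last an enzyme that halts viral RNA synthesis, were absent or nearly so in WT and plentiful in the libraries labelled KO. Hepatocyte genes such as the fibrinogen gene Fga and macrophage genes such as Marco were higher as well. Erythroid genes such as Slc4a1, the anion exchanger of red cells, were lower, while no globin gene was called. Mettl3 was not called. The libraries labelled KO disagreed on it, with 6.70 and 26.9 CPM against 29.4 and 24.9 CPM in WT. Whole liver also holds cells in which Vav-Cre does not act, and their part in these values was not tested.

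Mettl3 had a log2 fold change of -0.70 (SE 0.56, adjusted p 0.56 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with 6.70 CPM in KO 1, 26.9 in KO 2 and 29.4 and 24.9 in WT. Isg15 was at least 304-fold higher, at 184 ± 29 CPM against 0 (SD, n = 2, adjusted p 0.00038), and Ifit1 at least 194-fold, at 118 ± 30 CPM against 0 (0.0002). Rsad2 had a ratio of 259 (counting interval 88.5 to 1259), and Oas3, Ifi27, Saa3, Ms4a3, Tnfaip3, Cxcl10 and Ap5b1 were at least 77.0-, 65.5-, 32.4-, 31.5-, 25.1-, 24.8- and 14.7-fold higher. Rab30 and Dnaaf2 were at least 16.0- and 11.6-fold lower, Il1rl1 lower by -4.44, Muc6 by -3.62, Mylk3 by -2.79, Fbxo45 by -2.60 and the DNA repair gene Xrcc2 by -2.52 (SE 0.36, adjusted p 0.011). Rab30 and Dnaaf2 had 0 counts in KO input, but the J2 pull-downs of KO livers held them, so their loss from the tissue is not shown. Of 14657 genes, 173 were called, 90 higher and 83 lower; DESeq2 called 826. With library size alone 329 were called, 271 higher, and the median of all genes moved from 0.02 to 0.29. The 4 INPUT libraries fitted alone gave 25, where Saa3, Ms4a3, Rab30 and others above lost their calls, and leaving out KO 1 or KO 2 gave 32 and 29, WT 1 or WT 2 451 and 387. Abundant noncoding RNA took 40.6% and 42.2% of INPUT counts in WT and 28.7% and 31.0% in KO.

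Interferon-stimulated genes had 19 of 65 members higher and 0 lower (52 and 0 adjusted over the list alone), with a median of 3.00, or 2.88 with genes at 0 in one group set to their bound, and a camera adjusted p of 5.35e-57; this list call held with the correlation estimated (0.0141). Double-stranded RNA sensing genes had 5 of 25 higher (12 and 1 lower adjusted over the list alone; median 1.29, or 1.14 with bounds, 2.9e-08), with the sensor gene Ddx58 higher by 4.35 and Eif2ak2, the kinase that stops translation on double-stranded RNA, by 1.85. Hepatocyte genes had 5 of 27 higher (20 adjusted over the list alone; 0.76, 2.77e-12), with Fga higher by 1.35 and Afp by 0.76. Monocyte and macrophage genes had 3 of 26 higher (7 adjusted over the list alone; 0.96, 5.78e-08), with Lyz2 rising from 21.3 to 113 CPM and Marco by 2.06, and granulocyte genes 3 of 22 (9 adjusted over the list alone; 1.07, 3.36e-06). Inflammatory genes had 2 of 17 higher (3 and 1 lower adjusted over the list alone; 1.68, 0.00142). Erythroid genes had 6 of 30 lower (13 and 1 higher adjusted over the list alone; -0.58, 4.51e-08), with Slc4a1 falling by -1.26 (SE 0.15, adjusted p 0.0031) from 3076 to 1280 CPM. Globin transcripts, examined after their values were seen, made up 4.59% and 3.76% of INPUT counts in KO and 2.26% and 2.62% in WT, and the adult globin gene Hbb-bs had a log2 fold change of 0.73 that did not pass (adjusted p 0.105). Cell cycle genes had 0 of 42 called (8 lower adjusted over the list alone; -0.51, 2.23e-08). With the correlation estimated, the other 7 calls did not hold (adjusted p 0.0761 to 0.331).

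The 18 lists not called in INPUT had adjusted p from 0.062 for necroptosis and pyroptosis genes to 0.963 for the integrated stress response; necroptosis and pyroptosis genes were called higher with any of 6 libraries left out (0.0115 to 0.0158). Without INPUT WT 1, stromal (0.0187), megakaryocyte (0.0482) and quiescence genes (lower, 0.0446) were called, and without INPUT KO 2 lymphoid (0.0332) and immediate early genes (0.0304). Against the bulk LSK comparison, over 12313 genes tested in both, 59 were higher in both where 20.4 were expected (odds ratio 7.32, p 8.7e-19 by Fisher's exact test, two-sided), 19 without INPUT KO 1, 16 without KO 2, 109 without WT 1 or WT 2 and 39 without J2 KO 1 or KO 2. Lower in both were 45 where 17.3 were expected (4.68, p 1.5e-11), 7 without INPUT KO 1, 4 without INPUT KO 2 (p 0.239 by the same exact test) and 96 without INPUT WT 1. Spearman's correlation across genes was 0.20.

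The J2 comparisons asked which RNAs bind an antibody against double-stranded RNA, and whether binding differs without Mettl3. Malat1 and H19, long noncoding RNAs, and mt-Nd6, encoded on the light strand of mitochondrial DNA, were enriched in both genotypes. Transcripts of the adult globin gene Hbb-bt, of albumin and of ribosomal proteins were depleted. By edgeR without a block, no gene passed the test of the difference between genotypes. With the animal as a block, which follows the pairing of input and pull-down, 10 passed, Malat1 among them. The pull-downs also differed in make-up. Abundant noncoding RNA took 11.86% and 14.46% of J2 counts in WT and 5.755% and 5.977% in KO. Mitochondrial transcripts took 6.18% and 6.014% in WT and 3.634% and 3.804% in KO. Whether the calls made with the block follow from these shares was not tested. Counts were scaled to each library, so a change in the total RNA bound by J2 could not be seen.

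Mettl3 was enriched in neither genotype (log2 J2 over INPUT 0.04 in WT and 1.28 in libraries labelled KO, adjusted p 0.11 in the latter by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). mt-Nd6 (ENSMUSG00000064368) was enriched by 4.09 in WT (SE 0.16, adjusted p 1.7e-07), from 143 ± 13 to 2444 ± 46 CPM (SD, n = 2), and by 2.97 in KO (SE 0.16, adjusted p 6.8e-07), to 950 ± 13 CPM. H19 (ENSMUSG00000000031, chromosome 7) was enriched by 2.36 in WT and 2.35 in KO, and Malat1 (ENSMUSG00000092341, chromosome 19) by 1.30 and 2.52. Hbb-bt, the adult beta globin gene, was depleted by -3.63 in WT and -3.93 in KO, the albumin gene Alb by -2.79 and -2.83, Afp by -2.52 and -2.64, and the lipid carrier gene Apoe by -3.25 and -4.27. In WT, 3503 of 14657 genes were called, 1937 enriched and 1566 depleted; DESeq2 called 4108. In KO, 4462 were called, 2246 enriched and 2216 depleted; DESeq2 called 5153. Library size alone gave 2910 enriched and 998 depleted in WT (median from 0.10 to 0.52) and 2933 and 1730 in KO (median from 0.04 to 0.33). The WT count was 2297 without J2 WT 1 and 1855 without J2 WT 2, and the KO count 2744 without J2 KO 1 and 2750 without J2 KO 2.

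Genes absent from an input made up much of the strongest enrichment. In WT, Ap5b1, Ankrd6, the interleukin-15 receptor gene Il15ra, Mitf and Igip were at least 22.4-, 14.7-, 13.1-, 11.7- and 11.1-fold enriched, and the bile acid enzyme gene Cyp27a1 was at least 33.7-fold depleted. In KO, Rab30, Dnaaf2, Scml2, Ankrd6 and Igip were at least 60.3-, 40.7-, 26.2-, 25.2- and 22.7-fold enriched, and Crip1 was at least 109-fold depleted. The absence of Rab30 and Dnaaf2 from KO input, and of Ap5b1 from WT input, also gave their INPUT differences above, so these are not separate findings. Interferon-stimulated transcripts differed from one another: Trim25 was enriched by 1.76 in WT and 1.34 in KO and Dtx3l by 3.23 and 2.85, while Isg15 and Ifitm3 were depleted in KO by -3.69 and -4.18. Rsad2 had a ratio of 19.01 in WT (counting interval 6.31 to 93.8) and was enriched by 2.14 in KO (SE 0.30, adjusted p 0.00027).

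**Figure D5:**
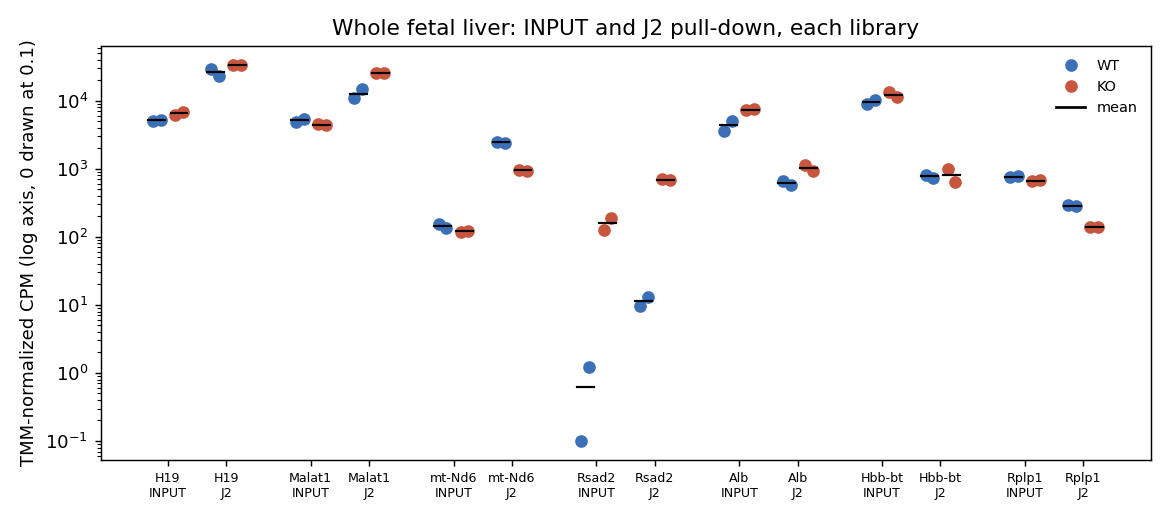
Points give the TMM-normalized CPM of 7 genes in each INPUT and J2 library (log axis, 0 drawn at 0.1), with the genotypes in separate colours. mt-Nd6 lay at a mean of 143 CPM in WT input and 2444 in WT pull-down, and Malat1, enriched by 1.30 in WT and 2.52 in KO, was higher in pull-down of both genotypes.

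Ribosomal protein genes and hepatocyte genes had the largest share of members depleted. Ribosomal protein genes had 60 of 83 depleted in WT (63 adjusted over the list alone; median -1.61, camera adjusted p 1.07e-33) and 63 in KO (69 adjusted over the list alone; -1.84, 1.37e-32), with 0 enriched in either. Hepatocyte genes had 21 of 27 depleted in WT (-2.43, 4.06e-29) and 22 in KO (-2.63, 3.43e-28), or 22 in both adjusted over the list alone. MYC targets and ribosome biogenesis had 22 of 38 depleted and 2 enriched in WT (25 and 2 adjusted over the list alone; -1.22, 1.47e-08) and 27 and 2 in KO (29 and 2 adjusted over the list alone; -1.77, 8.08e-11); the KO call held with the correlation estimated (0.0347) and the WT call did not (0.0554). Cell cycle genes had 20 of 42 depleted in WT (-1.02, 1.52e-05) and 25 in KO (-1.05, 2.87e-05), erythroid genes 13 of 30 (-0.98, 1.21e-06) and 16 (-0.999, 3.44e-06), granulocyte genes 10 of 22 (-1.65, 0.000609) and 12 (-2.24, 0.000125). Megakaryocyte genes had 11 of 24 depleted in WT (-1.53, 0.00222) and 9 in KO (-1.40, 0.0281), integrated stress response genes 9 of 32 (-0.69, 0.0298) and 15 (-1.10, 0.00821), and endothelial genes 5 of 17 in each (0.0297 and 0.0306). Adjusted over the list alone, WT and KO had 24 and 25 cell cycle genes depleted, 16 and 18 erythroid, 10 and 13 granulocyte, 11 and 10 megakaryocyte, 10 and 15 stress response and 6 and 5 endothelial genes. The WT stress response call was lost with library size alone (0.0599) and without INPUT WT 2 (0.131) or J2 WT 1 (0.0569), and the KO endothelial call without INPUT KO 2 (0.0738).

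In KO, m6A genes, with 9 of 23 enriched and 1 depleted (0.83, camera adjusted p 0.00966), and SOCS genes, with 3 of 7 enriched (2.22, 0.00933; 4 adjusted over the list alone), were called. In WT they had 0.0739 and 0.0535, but m6A genes were called there with library size alone (0.0135) and without J2 WT 1 (0.0323), and SOCS genes without INPUT KO 1 (0.0368) or INPUT KO 2 (0.0222). Apart from the MYC call in KO, the adjusted p of the called lists with the correlation estimated lay between 0.0554 and 0.382 in WT and between 0.0865 and 0.378 in KO. Interferon-stimulated genes, with 4 of 65 enriched and 4 depleted in WT (median 0.00, 0.951) and 5 and 7 in KO (-0.25, 0.487, a median that became 0.04 with library size alone), and double-stranded RNA sensing genes (0.99 and 0.842) were called in neither. The other lists had adjusted p of at least 0.334 in WT and 0.0876 in KO. With a library left out, monocyte and macrophage genes were called depleted in KO (without INPUT WT 1, 0.0363, INPUT WT 2, 0.0381, or J2 KO 1, 0.0440) and in WT (without INPUT WT 1, 0.0472), and stromal genes in WT (without INPUT WT 2, 0.0330).

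The interaction tested the difference between enrichments. For Mettl3 it was 1.24 (SE 0.78, adjusted p 0.66 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Malat1 had 1.22 (SE 0.19, adjusted p 0.26), mt-Nd6 -1.12 (SE 0.21, adjusted p 0.30), the mitochondrial ribosomal RNA mt-Rnr1 -0.97 (SE 0.13, adjusted p 0.16), Rsad2 -2.05 (adjusted p 0.49), H19 -0.01 and Alb -0.05. None of 14657 genes was called by edgeR, with 1340 at a raw p under 0.05; DESeq2 called 76, and the animal as a block gave 10, 4 higher and 6 lower, among them Malat1 (1.23, adjusted p 0.00123) and mt-Rnr1 (-0.98, 0.00131). Leaving out J2 WT 1 gave 9 genes, INPUT WT 2 3 and J2 WT 2 1. With library size alone the median of all genes moved from -0.10 to -0.23 and 3 genes were called. None of the lists was called; MYC targets had the smallest adjusted p (0.0664, 0.63 with the correlation estimated, 0.0121 with the animal as a block), and adjusted over the list alone hepatocyte genes had 4 of 27 lower.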

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

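Of the tests below, those of other splits of the bulk samples, of strong and weak H3K4me3 windows, of marked windows, of single bulk libraries, of swapped labels and of tags outside the deleted part were chosen only after the result was seen. Genes called in opposite directions in sorted LSK cells and in whole fetal liver stood out because a deficient group moved up in one tissue and down in the other. 5 genes were higher in LSK cells and lower in liver: the DNA repair genes Xrcc2 (log2 fold change 0.39 in LSK, -2.52 in liver), Gen1 (0.29, -1.62) and Rfwd3 (0.17, -1.16), the glycosylation gene C1galt1 (0.37, -1.33) and the polyamine enzyme gene Odc1 (0.62, -0.82). 4 genes were lower in LSK cells and higher in liver: Cd5l of macrophages (-2.46, 1.73), the matrix gene Fn1 (-1.12, 0.96), Cox6b2 (-0.63, 1.93) and Zfp113 (-0.41, 2.15). Of the 12313 genes tested in both tissues, 2953 were called higher and 2625 lower in LSK cells. With so many calls, some opposite pairs arise by number alone, and these genes may be such overlaps. The number expected was not computed, while 59 genes were higher and 45 lower in both tissues. The difference itself was not tested for any of the genes above, since the tissues were counted in separate tables, and no explanation was tested.

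The number of genes called in bulk LSK cells was compared with other splits of the samples. The real split of 3 KO and 3 WT libraries called 6367 genes and the highest of the other splits 0, so 1 of 10 splits gave as many. With 10 splits the share cannot fall under 0.05, so they are too few to decide.

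H3K4me3 windows with a strong signal were higher in KO and weak ones lower, and of windows called lower 72.7% had a mean log2 CPM under 2. Of the 51038 windows tested, 16260 lay at 0 to 1 and 9565 at 1 to 2, so that percentage partly follows from their number. Strong windows higher and weak ones lower is what a larger share of background reads in the WT libraries would give. Such a share may account for much of the pattern over all windows. A gain of the mark at all marked windows stays open: windows with a log2 CPM of 6 or more had a median log2 fold change of 0.33, and with no external standard in the table a gain cannot be told apart from a lower background. Interferon-stimulated genes were higher on marked windows alone, normalized on those windows (camera adjusted p 1.57e-26 with the preset correlation, 0.379 with the correlation estimated), which a shared background does not give.

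Interferon-stimulated genes were higher in the single-cell libraries labelled KO, both of which were female while the WT libraries were male. Sex as the cause is argued against by bulk libraries that held transcripts of both sexes, where KO 2 and 3 against WT 1 and 2 gave 91.3% of the list higher (63 of 69, median log2 fold change 1.18), although these were not matched for sex (Y-linked Ddx3y at 17.0 and 15.1 against 57.1 and 36.6 CPM). Over the mean of WT, the list's median was 0.84 in KO 1, which held female transcripts only, against 1.23 and 1.18 in KO 2 and 3, and -0.08 in WT 3, which held male ones only, against 0.08 and 0.01 in WT 1 and 2. In INPUT, the list was higher in KO within males (59 of 65 genes, median 3.28) and within females (64 of 65, median 3.04), with 1 library of each genotype per sex. Sex remains an open explanation for single genes of the single-cell comparison, where it follows genotype.

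Mettl3 tags were not lower in the single-cell libraries labelled KO, with a log2 fold change of 0.74. Swapped genotype labels are argued against by the other genes, whose changes followed those of bulk with a Spearman correlation of 0.667 across genes; a swap would give a negative one. Tags outside the deleted part of Mettl3 could give this result, and the value of 0.74 cannot be told apart from it, because the table holds no positions of tags within a gene.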

How the results depend on the processing

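Alternatives chosen only after the results were seen were marked windows, sex as a term, genes of chromosomes X and Y or cells with most counts left out, abundant noncoding loci left out, clustering without sex transcripts, and DESeq2 within classes. The bulk count and, left-out libraries aside, the J2 counts in each genotype stayed within 1.5 times under every alternative run. No cluster share was called under any. Agreement of bulk with H3K4me3, and of higher genes with INPUT, passed Fisher's exact test under all, though its counts moved. The cause of the moves below was not tested unless stated.

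With DESeq2, calls moved from 4024 to 802 for H3K4me3, 173 to 826 in INPUT, 0 to 76 for the interaction, 1 to 310 in single-cell sums and 602 to 255 within classes. The replicate number as a block gave 20840 for H3K4me3 (12424 higher and 8416 lower, against 1648 and 2376), 117 for single-cell sums and 1788 within classes (161 erythroid-like, against 242, 941 stem and progenitor-like, against 158, 352 lymphoid-like, against 44, and 333 monocyte-like, against 157). The labels give the samples only a number in common. Deviations of same-numbered KO and WT bulk libraries correlated at 0.229, 0.0957 and 0.0435, and KO 2 followed WT 3 more closely, at 0.170. Same-numbered libraries correlated at 0.301 for H3K4me3 and 0.260 for single cells, where 2 pairs are too few to decide. In single cells, the cluster with high Fos, Egr1 and Klf2 held 43.0% of WT 1 and 12.4% of KO 1 but 0.82% of WT 2 and 0.64% of KO 2. Erythroid-like and stem and progenitor-like shares also split by number. A batch shared by number would leave its spread in the single-cell tests without the block, which could then call fewer genes. For the interaction, the animal as a block gave 10. The block moved no other count of genes by more than 1.5 times, and of the J2 calls in the text it changed only those given beside them. Without a low-count filter, INPUT gave 798, the interaction 103 and single-cell sums 11. With library size alone, INPUT gave 329 and the interaction 3.

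For H3K4me3, all distinct windows gave 12979, where more windows were tested and starts of a gene share reads, and marked windows 666, where fewer were tested. The 4 INPUT libraries alone gave 25, from a fit with fewer libraries. Sex as a term gave 3 for the interaction, and J2 libraries without inputs gave 1469, which leaves in the difference between the inputs. There Ddx58 went from -2.30 to 2.09 and Tnfaip3 from -6.30 to 2.74. Single-cell sums gave 7 without the 5% of cells with most counts and 0 without genes of chromosomes X and Y, where Xist was removed.

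Leaving out each library in turn gave 1078 to 3855 for H3K4me3, 29 to 451 in INPUT, 1855 to 3600 for J2 in WT, 2744 to 5599 for J2 in KO, 0 to 9 for the interaction, 0 throughout for single-cell sums and 439 to 1186 within classes. A group left with 1 library is assumed to vary like the others. Genes lower in both bulk and INPUT ranged from 4 (Fisher's exact p 0.239) to 96, and higher in both from 16 to 109; bulk and H3K4me3 shared 97 to 539 higher and 55 to 148 lower.

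List calls with the correlation estimated went from 15 to 0 in bulk, 19 to 0 for H3K4me3, 8 to 1 in INPUT, 9 to 0 for J2 in WT, 11 to 1 for J2 in KO and 10 to 0 in single-cell sums. With fry, 0 were called for H3K4me3 and 0 in single-cell sums. The replicate number as a block ended the endothelial call for H3K4me3 (camera adjusted p 0.0933) and made hepatocyte genes a call in bulk (median -0.88, 0.0264). In single-cell sums it made calls of erythroid genes (-0.68, 0.000132) and mitochondrial transcripts (-0.26, 0.0141). Marked windows gave 8 lists, and there the median of cell cycle (S and G2/M) became -0.060 (camera adjusted p 0.0256). Lists of the interaction, 0 as reported, numbered 3 with library size alone, 1 with the block, 1 with sex as a term and 0 to 2 with libraries left out. At an adjusted p under 0.1, 3 genes were lower in both bulk and single cells (Fisher's exact p 0.0152) and 3 higher in both (0.0783). The genes lower in single cells at that threshold included the Y-linked Ddx3y and Eif2s3y, which follow the sex of those libraries.

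Over named genes and settings, 8120 values kept direction and side of the threshold, 525 fell short of it, 207 passed it and 2 reversed. For lists, 2056 were kept, 134 fell short, 69 passed and 1 reversed. On simulated data, 2-fold changes were recovered at 80.6% in bulk, 55.2% for H3K4me3, 5.97% in single-cell sums, 1.49% for J2 in either genotype and 0% in INPUT and for the interaction.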

Other observations

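All values here were chosen after the data were examined, and no explanation was tested. Malat1 made up 3.00% and 3.06% of J2 counts in KO and 1.22% and 1.51% in WT, and 0.447% and 0.419% of INPUT counts in KO and 0.411% and 0.418% in WT. H19 stood at 33210 and 33900 CPM in the J2 libraries of KO and at 29520 and 23350 CPM in those of WT.

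Cells of the single-cell libraries showed no mixing of sexes. Xist was counted in 38.6% and 46.4% of KO cells and in 0% of WT cells, Y-linked transcripts in 19.4% and 16.8% of WT cells and in 0% of KO cells, and 0% of cells held both. The cluster with high Fos, Egr1 and Klf2 held 43.0% of WT 1 and 12.4% of KO 1 but 0.82% of WT 2 and 0.64% of KO 2.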
